A study of Homo sapiens with 8 samples.

How the data were processed

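RNA was measured in 8 libraries of astrocytes differentiated from human pluripotent stem cells of the H7 line, 4 labelled E50K and 4 labelled isogenic control. Per the labels' protocols, the cells were grown on laminin for 3 weeks and total RNA was isolated from the lysed cells with the PicoPure kit. Per the submitters' processing notes, the reads were aligned with STAR to GRCh38 and counted with featureCounts. The versions, the annotation release, the library kit and the strand setting are not given in the sources used here. The authors deposited raw read counts per gene, whole numbers with no normalization, in 1 table with a column for each library, and per the file headers each gene has its exon coordinates and a length. All columns of sample values were used. Each column was matched to its sample by the description in the labels.

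The table held 28058 genes. Of its names, 27 had been turned into calendar dates, and all 27 were restored from the gene's coordinates in the table and a list of reference genes. A gene that the annotation places on more than 1 sequence (1310 genes) may lose reads that align to several places, which was not tested. Only 206 of these (15.7%) passed the filter below, against 55.5% of the other genes, so genes of the HLA region in particular are uncertain. Because the strand setting is not known, genes with much of their exon length shared with another gene on either strand are named with that share. The table held 2 genes of the mitochondrial genome, both of ribosomal RNA. XIST and Y-linked genes entered the fit and are not reported.

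The groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, which left 15040 genes (53.6%) with at least 99.94% of the counts of each library. Library sizes were scaled by TMM, and a robust quasi-likelihood fit with group as its 1 term was tested with glmQLFTest, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The biological coefficient of variation was 20.6%. Levels are in CPM, the usual unit of counts scaled to the library total, and use the TMM-scaled library sizes, and log2 CPM for scores and principal components used a prior count of 2. The floor is 3 counts per library and covers counting error only. The replicates were compared first: within a group, every pair of libraries differed by 15.26 to 128.8 times the sampling noise (chi-square per degree of freedom), with Pearson correlations across genes of 0.957 to 0.988, so none was counted as the same library deposited again. Separate preparations of 1 culture could also differ by more than sampling noise, so this does not show separate cultures. With 4 against 4 libraries, the smallest two-sided p of an exact permutation test is 0.0286.

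Before the data were examined, 36 gene lists were written down, of cell type markers and of pathways related to astrocytes, optineurin and stress. They were tested with camera and fry from limma 3.58.1, camera with a preset correlation of 0.01 and again with an estimated one, and adjusted over the 34 lists with at least 2 tested genes. The score of a list is the mean of its members' centred log2 CPM. The genes named in the text follow a rule fixed at the same time. It takes OPTN, the 10 largest rises and 10 largest falls and the 10 smallest p-values among genes past the test with a mean of at least 5 CPM in the higher group, no overlap between the groups and an approved symbol, and in each list up to 4 members with the smallest p and any member needed to describe it. Some genes that meet the rule are not reported here. Members needed to describe a list were picked after their values were seen. A further 6 lists were also written after the data were seen, and they appear only among the closing observations and in the plot of list scores.

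Medians per autosome were compared with 10000 random gene sets of the same size and expression. Medians of 10 neighbouring tested genes were compared with 1000 random orders of the genes. On simulated counts for the 15040 genes of the E50K against control comparison, the same steps called 67% of 100 genes changed 2-fold and 89% of 100 genes changed 4-fold, and 0.637% of the calls were false. No other genes were changed there, a far smaller share than the 40.3% called in the data. These rates depend on that share and need not hold for the real comparison. In a further draw of this simulation, camera called 1 of 30 unchanged lists and 4 of 4 lists of 20 genes changed 1.5-fold. Its genes were drawn independently, whereas the correlation estimated from the data was 0.834 for cell cycle genes and 0.514 for NF-kB targets. It therefore does not check the preset correlation for such lists. Alternatives were other scalings (DESeq2 size factors, library size, upper quartile), no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a replicate block, an adjusted p under 0.01, a 2-fold minimum, and each library or each pair of equal number left out. Thinned counts and a cell cycle covariate were added after the data were seen. All 35 splits of the 8 libraries into 4 and 4 were also fitted.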

Results

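The series measured RNA in astrocytes made from H7 cells, an established human pluripotent stem cell line, to ask which genes differ between astrocytes that carry the E50K change in optineurin and isogenic astrocytes with wild-type optineurin. Optineurin, encoded by OPTN, is a receptor that links ubiquitin-tagged cargo to the autophagy machinery, and E50K is a known cause of inherited normal-tension glaucoma. The cells had been plated on laminin for 3 weeks before RNA was taken from the dish. There were 4 E50K libraries and 4 control libraries, numbered 1, 2, 4 and 5 in each group. Total gene counts ran from 28935950 to 59524917 in the control libraries and from 27099286 to 67095542 in the E50K libraries, so that 3 counts corresponded to between 0.0441 and 0.113 CPM. Reads of mitochondrial ribosomal RNA made up 1.19% ± 0.229 (SD, n = 4) of control counts and 1.60% ± 0.178 (SD, n = 4) of E50K counts (exact two-sided permutation p = 0.0571). The first principal component of log2 CPM held 67% of the variance and separated the groups, and on the second, with 13.6%, E50K replicate 1 stood at 61.7 against -25.5 to 4.89 for the other 7 libraries.

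The transcriptomes of the E50K and control astrocytes differed widely. By camera with its preset correlation, the lists of cell division, NF-kB and TGF-beta genes were lower in the E50K astrocytes, and those of astrocyte markers, glutamate and ion handling and cholesterol synthesis were higher. All 6 of these calls were lost with a correlation estimated from the data (adjusted p 0.202 to 0.484). Of 15040 genes tested, 3066 rose and 3002 fell in E50K, which is 40.3% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). Among them 1082 rose and 1143 fell by at least 2-fold. The 4 libraries of each group did not overlap for 5839 genes, 38.8% of those tested, where chance gives 2.9%. Without E50K replicate 1, the library that stood apart, 3567 genes rose and 3678 fell. The labels put the letters exp before the number of each library, in both groups. They do not say what the letters stand for or whether the libraries of a group came from separate cultures or clones. The edgeR p-values therefore measure the spread between these libraries, part of which may be technical.

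OPTN itself (chromosome 10, 13100082 to 13138276, plus strand, GRCh38) was at 177 CPM ± 25.6 in control and 159 CPM ± 29.0 in E50K astrocytes (SD, n = 4 each). Its log2 fold change was -0.15 (SE 0.14), which did not pass the test (edgeR adjusted p = 0.414). An amino acid change need not alter the level of its transcript, so this level does not check the labels. Without both libraries of replicate 1 the log2 fold change was -0.33 and passed (adjusted p = 0.0492), and without both libraries of replicate 5 it was 0.008 (adjusted p = 0.974), the lowest and highest adjusted p over 26 alternatives.

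The largest rises included USP51, a deubiquitinating enzyme gene on the X chromosome, which had 0 counts in all 4 control libraries and 10.7 CPM ± 1.46 in E50K (SD, n = 4), at least 120-fold higher against 3 counts per library. CBLN4, which encodes a secreted synapse organiser of the cerebellin family, rose from 0.166 ± 0.146 to 58.0 ± 13.2 CPM, a log2 fold change of 8.51 (SE 0.43; edgeR adjusted p = 7.67e-06). The oligodendrocyte-lineage transcription factor gene OLIG1 rose from 0.143 to 6.34 CPM. OMG, the gene of oligodendrocyte myelin glycoprotein, rose 14.4-fold, SORCS3, a sorting receptor gene, 10.7-fold and FAM69C from 1.91 to 21.4 CPM. RYR1, which encodes an intracellular calcium release channel, rose 12.6-fold, with a log2 fold change of 3.65 that became 4.27 without control replicate 2.

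The largest falls among genes of at least 5 CPM were in KCNA1, a voltage-gated potassium channel gene, from 6.22 ± 2.97 to 0.0257 ± 0.0515 CPM, and in SEMA3C, a secreted guidance cue gene, from 5.58 ± 4.01 to 0.0412 ± 0.0643 CPM (SD, n = 4 each). PENK, which encodes the enkephalin precursor, fell from 16.1 to 0.169 CPM, and the cytokine gene IL11 from 113 to 2.53 CPM. ITIH5, a hyaluronan-binding protein gene, was 49.3-fold lower, the tight junction gene CLDN1 43.9-fold, CPQ 36.1-fold and the neurexin-family gene CNTNAP2 30.7-fold. The fitted log2 fold changes of several of these moved by more than 1.5-fold with 1 library left out: KCNA1 from -7.15 to -10.75, PENK from -6.26 to -7.67 and CPQ from -5.17 to -6.06 without E50K replicate 2, SEMA3C from -7.07 to -8.26 without E50K replicate 5, and IL11 from -5.46 to -4.83 without control replicate 5. All 5 kept an adjusted p under 0.05 there. In CBLC, CYTL1 and FOXQ1, which fell, all E50K libraries had 0 counts; they were singled out after their values were seen.

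The smallest p-values belonged to genes with large and even changes. PCDHGB6, a clustered protocadherin gene, rose 9.4-fold from 30.3 ± 3.56 to 285 ± 24.2 CPM (SD, n = 4; edgeR adjusted p = 9.8e-07), while its neighbour PCDHGB7 fell 13.1-fold. Both share exons with other members of the cluster over 47% and 43.9% of their length, so their counts are uncertain. The imprinted gene DLK1, an inhibitor of Notch signalling, fell 12.7-fold from 852 ± 168 to 67.3 ± 5.61 CPM. Falls were also seen in the small GTPase gene DIRAS2 (24.4-fold), the kinase gene PAK3 (4.45-fold, from 584 to 131 CPM), GUCY1A2, a subunit gene of soluble guanylate cyclase (8.73-fold) and SLFN11 (38.2-fold).

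**Figure D1:**
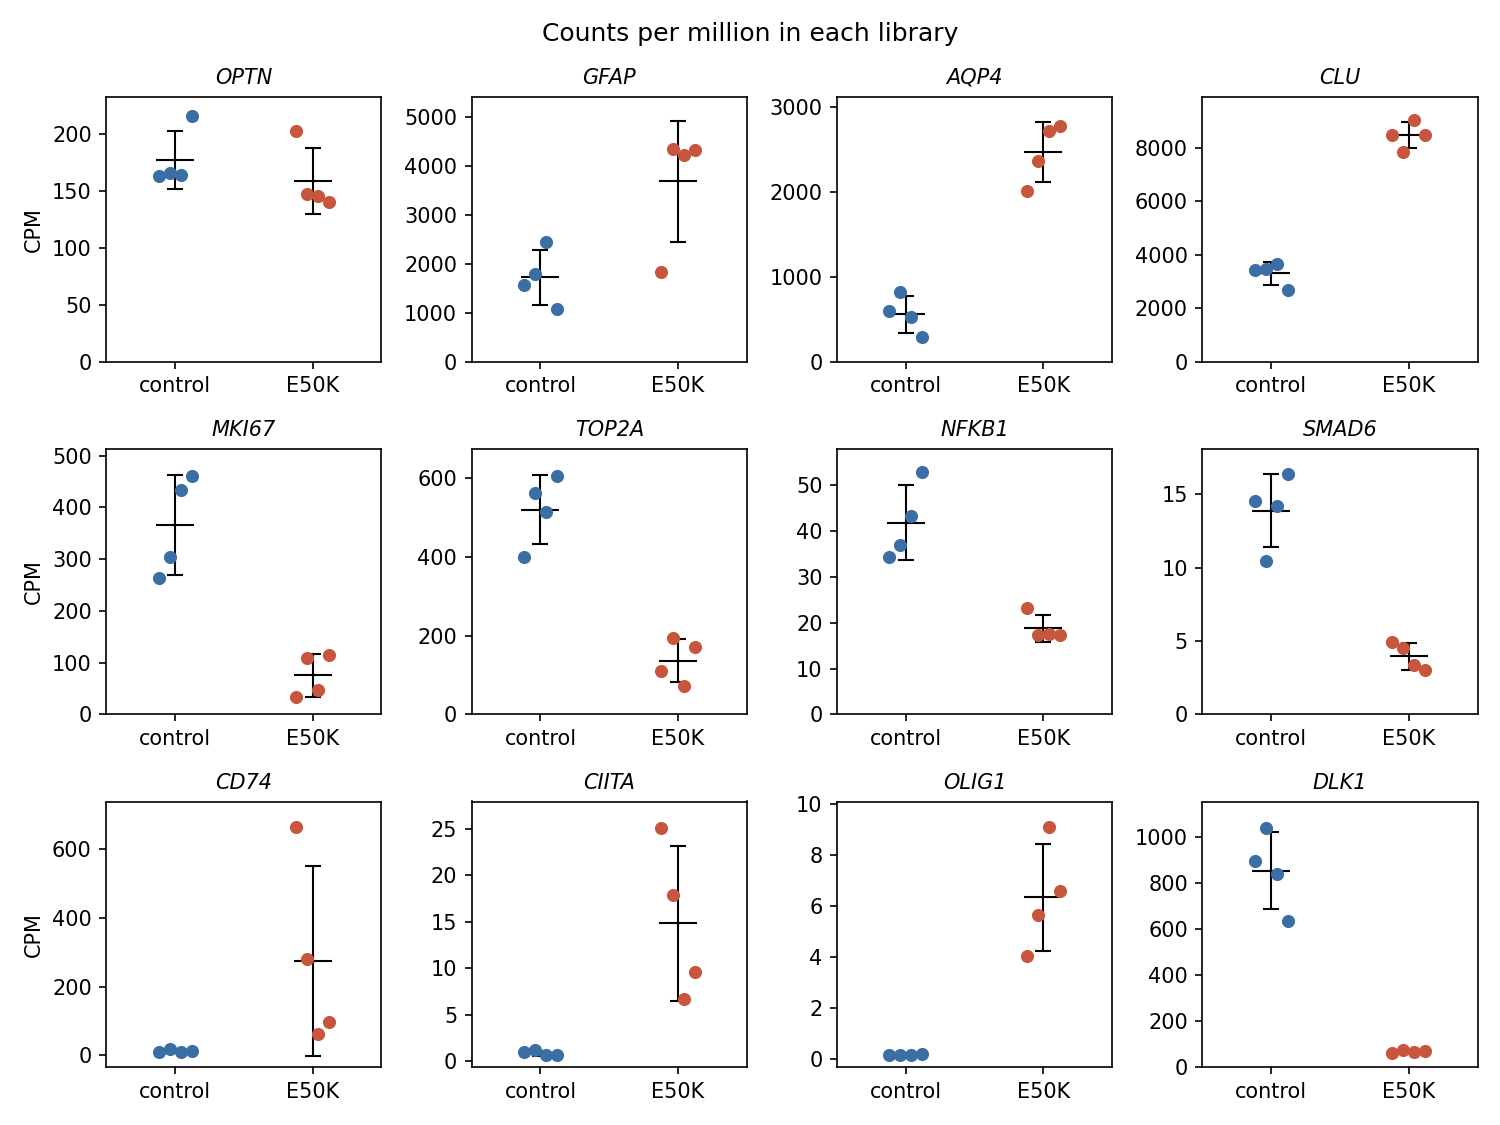
CPM (y axis, linear) of 12 genes in each of the 4 control (blue) and 4 E50K (red) libraries; the horizontal bar is the mean and the whiskers 1 SD. Levels of OPTN overlap between the groups, as do those of GFAP, where E50K replicate 1 lies at 1836 CPM, while the other 10 genes separate the groups, including CLU at 3308 against 8465 CPM and DLK1 at 852 against 67.3 CPM.

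The fixed gene lists were then compared. Of 34 lists with at least 2 tested genes, 10 passed camera with its preset correlation of 0.01, and 0 passed with a correlation estimated from the data, where 3 had an unadjusted p under 0.05. As many lists passed in 15 of the 35 splits of the 8 libraries into 4 and 4, the real split included. The splits therefore do not show the number of lists past camera to be beyond chance. Splits that divide the groups unevenly keep part of the group difference, so they are not a clean measure of chance. With the test fry 21 lists passed, which says that the genes of a list moved, on balance, one way, without comparing them with other genes. Counts of members adjusted over the list alone were the same as those adjusted over all tested genes except where given.

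All 28 cell cycle genes fell in the E50K astrocytes, with a median log2 fold change of -2.09 (camera adjusted p = 5.79e-25; adjusted p = 0.348 with an estimated correlation). MKI67, the gene of the proliferation marker Ki-67, fell 4.82-fold from 366 ± 96.8 to 75.7 ± 41.5 CPM (SD, n = 4), and TOP2A, the topoisomerase gene needed to separate replicated chromosomes, 3.81-fold from 521 to 137 CPM. The cyclin gene CCNA2 was 4.71-fold lower and the mitotic motor gene CENPE 5.34-fold lower. The score of the list ran from 0.79 to 1.19 in the control libraries and from -1.80 to -0.42 in E50K (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give).

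Markers of astrocytes moved the other way. Of 25 tested, 19 rose, 2 fell and 4 did not pass, with a median log2 fold change of 1.10 (camera adjusted p = 3.89e-08; adjusted p = 0.202 with an estimated correlation). Adjusted over the list alone, 19 rose and 3 fell. AQP4, the water channel of astrocyte endfeet, rose 4.39-fold from 562 ± 216 to 2468 ± 353 CPM (SD, n = 4), and HEPACAM, an astrocyte adhesion molecule gene whose exons overlap those of HEPN1 by 40.3%, rose 5.61-fold. CLU, the gene of clusterin, rose 2.56-fold to 8465 CPM. GFAP, the main intermediate filament gene of astrocytes, rose 2.14-fold (edgeR adjusted p = 0.0172), but the groups overlapped, with E50K replicate 1 at 1836 CPM, the other E50K libraries at 4232 to 4340 CPM and the controls at 1080 to 2441 CPM. GFAP lost its call in 5 of 26 alternatives, among them those without both libraries of replicate 2 or of replicate 5 (adjusted p = 0.0856 and 0.105, within 0.000955 to 0.105). The 2 markers that fell were ID3, an inhibitor of basic helix-loop-helix factors (log2 fold change -2.77, and -3.69 without E50K replicate 2), and DIO2, the deiodinase gene that activates thyroid hormone (-1.34).

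Genes for the handling of glutamate and ions, which share 5 tested genes with the astrocyte list, were also higher. Of 18 tested, 13 rose, 1 fell and 4 did not pass, with a median log2 fold change of 1.10 (camera adjusted p = 5.32e-05; adjusted p = 0.348 with an estimated correlation); adjusted over the list alone, 14 rose and 3 fell. The glutamate transporter genes SLC1A2 and SLC1A3 rose 3.44-fold and 2.79-fold, SLC1A3 reaching 4216 CPM ± 962 (SD, n = 4). GLUL, the gene of glutamine synthetase, rose 3.43-fold, the inward rectifier potassium channel gene KCNJ10 2.89-fold, and ATP1B2, a sodium pump subunit gene, 3.26-fold. The chloride importer gene SLC12A2 was the 1 member that fell (2.97-fold lower).

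Of 24 genes of cholesterol synthesis and its control, 17 rose, 1 fell and 6 did not pass, with a median log2 fold change of 0.49 (camera adjusted p = 0.000116; adjusted p = 0.484 with an estimated correlation). HMGCS1, the synthase gene of the mevalonate pathway, rose 2.76-fold from 868 ± 170 to 2391 ± 412 CPM (SD, n = 4), INSIG1, a sterol-responsive regulator gene, 2.53-fold, and LSS, which encodes the enzyme that closes the sterol rings, 1.75-fold.

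**Figure D2:**
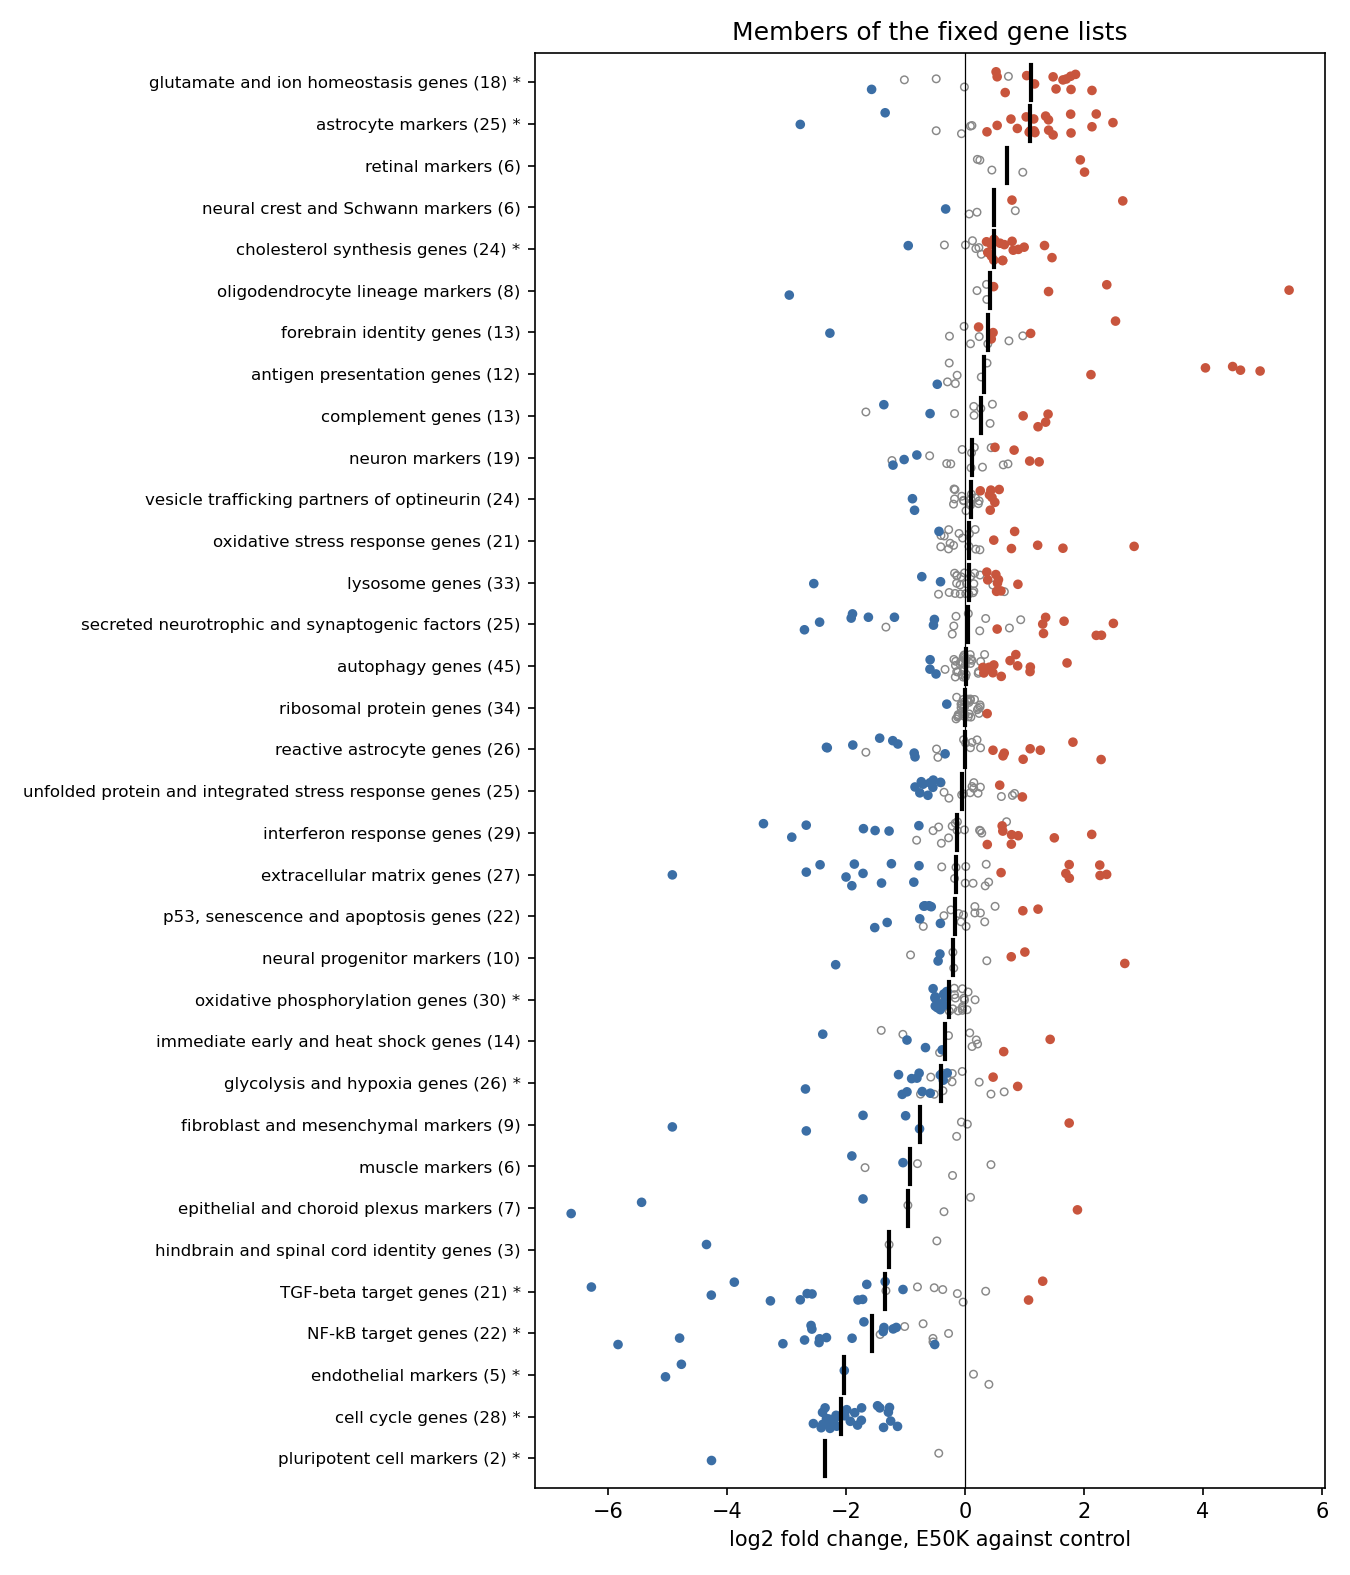
Log2 fold change, E50K against control (x axis), of every tested member of the 34 fixed lists (y axis, number tested in brackets), ordered by median (black bar); filled points passed the edgeR test, red higher and blue lower, open grey points did not, and a star marks lists past camera with its preset correlation. Cell cycle genes lie below 0 throughout (median -2.09), and astrocyte markers lie mostly above it (median 1.10).

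Targets of NF-kB, the transcription factor of inflammatory signalling in whose pathway optineurin also acts, were lower. Of 22 tested, 16 fell, 0 rose and 6 did not pass, with a median log2 fold change of -1.56 (camera adjusted p = 1.92e-06; adjusted p = 0.447 with an estimated correlation). NFKB1, the gene of the p50 subunit, fell 2.23-fold from 41.9 ± 8.20 to 18.8 ± 2.89 CPM (SD, n = 4). TNFAIP3, the gene of the feedback inhibitor A20, had a log2 fold change of -2.59 and -3.20 without E50K replicate 1. The cytokine gene IL1A fell from 6.13 to 0.218 CPM, with a log2 fold change of -4.80 that became -6.05 without E50K replicate 1. CCL2 and IL6 did not pass (log2 fold changes -0.54 and -0.70) but did without E50K replicate 1 (-1.37 and -2.95, adjusted p = 0.015 and 0.0191, within 0.0109 to 0.779 and 0.0154 to 0.882), and their E50K libraries were spread widely: IL6 stood at 23.7 CPM in E50K replicate 1 and at no more than 3.50 CPM in the other E50K libraries.

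Of 21 targets of TGF-beta and BMP signalling, 12 fell, 2 rose and 7 did not pass, with a median log2 fold change of -1.34 (camera adjusted p = 0.00218; adjusted p = 0.348 with an estimated correlation); adjusted over the list alone, 2 rose and 13 fell. SMAD6, an inhibitory SMAD gene, fell 3.48-fold from 13.9 ± 2.50 to 3.96 ± 0.927 CPM (SD, n = 4). CTGF, a matricellular protein gene, fell 6.29-fold, with a log2 fold change of -2.65 that became -3.46 without E50K replicate 1, and ID1 had -3.88, which became -5.20 without E50K replicate 2. TGFB2, which encodes a TGF-beta ligand, rose 2.47-fold from 202 to 499 CPM, although TGFB2-AS1 and TGFB2-OT1 overlap 25.8% of its exons. Markers of other cell types moved with this list and the NF-kB list: the fibroblast and mesenchymal score ran from 0.407 to 0.751 in control and from -0.835 to -0.29 in E50K (exact two-sided permutation p = 0.0286), and the endothelial score from 0.652 to 1.786 and from -1.806 to -0.301 (exact two-sided permutation p = 0.0286).

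The lists of glycolysis and hypoxia genes and of nuclear genes of oxidative phosphorylation passed camera in the downward direction, but their scores overlapped between the groups. E50K replicate 1 lay among the controls, at 0.128 for glycolysis and hypoxia against 0.125 to 0.36 (exact two-sided permutation p = 0.0571) and at 0.164 for oxidative phosphorylation against 0.021 to 0.168 (exact two-sided permutation p = 0.114). Of 26 glycolysis and hypoxia genes, 12 fell, 2 rose and 12 did not pass (median log2 fold change -0.40, camera adjusted p = 0.00786; adjusted p = 0.532 with an estimated correlation), and adjusted over the list alone 15 fell and 2 rose. The hexokinase gene HK2 fell 2.08-fold, the glucose transporter gene SLC2A1 1.97-fold, LDHA, a lactate dehydrogenase gene, 1.75-fold and NDRG1, a hypoxia-induced gene, 6.42-fold, while BNIP3, a mitophagy receptor gene, rose 1.85-fold. Of 30 oxidative phosphorylation genes, 12 fell, 0 rose and 18 did not pass (median -0.28, camera adjusted p = 0.0249; adjusted p = 0.774 with an estimated correlation), including the complex I gene NDUFS1 (1.33-fold lower) and the ATP synthase gene ATP5F1B (1.42-fold lower). The oxidative phosphorylation list did not pass fry (adjusted p = 0.0837). Its camera call was lost without control replicate 1, E50K replicate 4 or E50K replicate 5 (camera adjusted p = 0.0534, 0.0556 and 0.0865), within 0.000419 to 0.129 over the alternatives with the preset correlation.

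**Figure D3:**
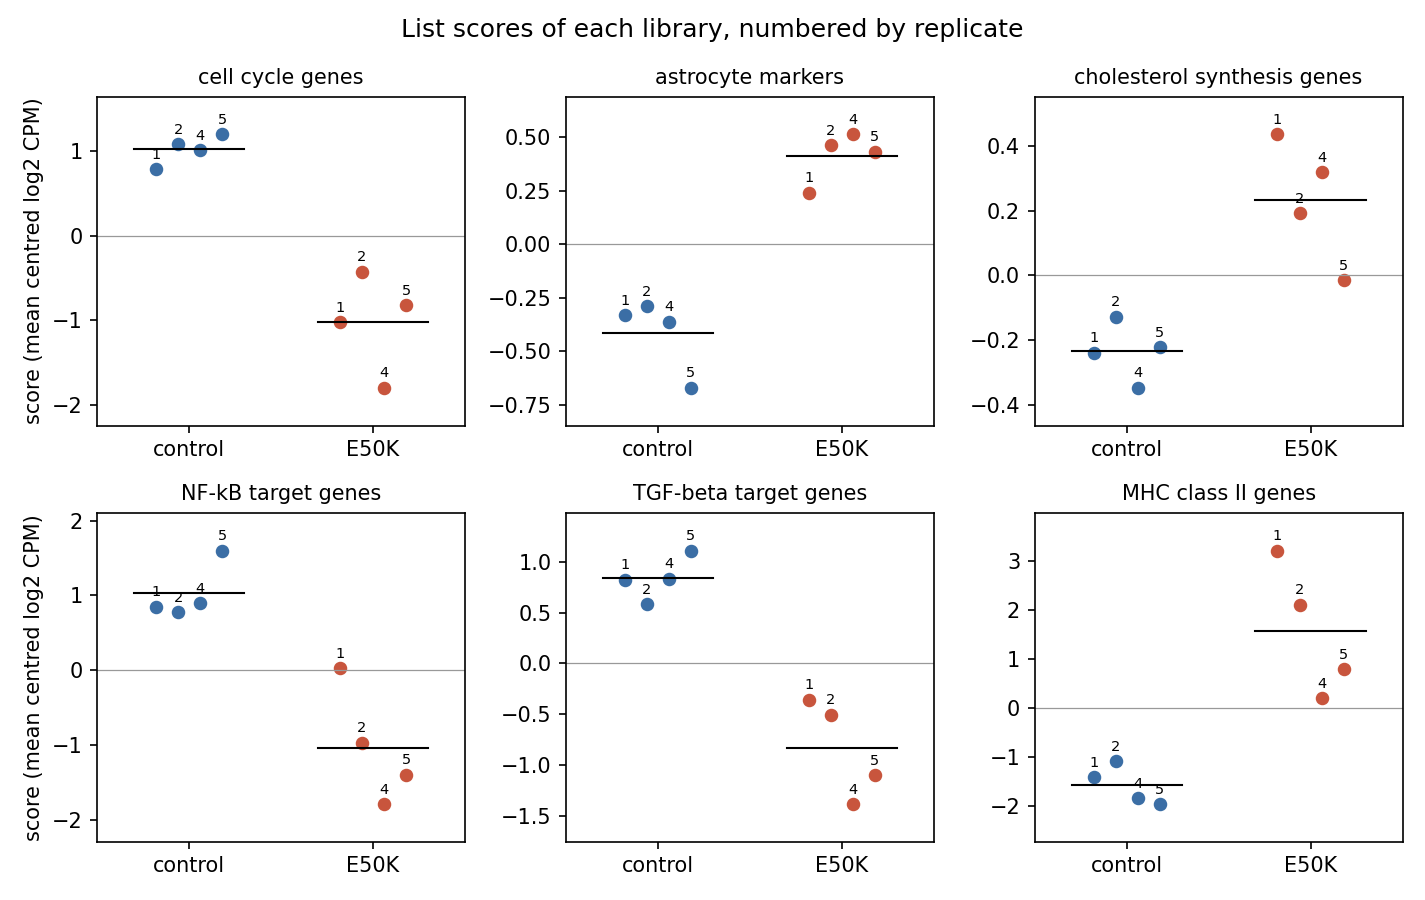
List scores (y axis, mean of log2 CPM centred per gene) of 6 lists in each control (blue) and E50K (red) library, numbered by replicate, with the group mean as a bar; the MHC class II list was chosen after the data were seen. In each panel the groups do not overlap, and on the NF-kB list E50K replicate 1 lies closest to the controls.

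Genes of autophagy and of the lysosome, the processes optineurin serves, included members that rose without the lists passing camera. Over all tested genes 40.3% passed the edgeR test, rises and falls together, a larger share than in any list of this paragraph. Of 45 autophagy genes, 13 rose, 3 fell and 29 did not pass (median log2 fold change 0.01, camera adjusted p = 0.185). PINK1, a kinase gene of mitophagy, rose 2.14-fold, although PINK1-AS and MIR6084 overlap 62.2% of its exons, and ULK2, a kinase gene that starts autophagy, rose 1.81-fold. TAX1BP1, an autophagy receptor gene related to OPTN, fell from 223 to 148 CPM. The receptor gene SQSTM1 and the kinase gene TBK1, whose product phosphorylates optineurin, did not pass (log2 fold changes 0.09, SE 0.19, and -0.12, SE 0.12); for SQSTM1 the value was -0.15 without E50K replicate 1. Of 33 lysosome genes, 8 rose, 3 fell and 22 did not pass (median 0.06, camera adjusted p = 0.371), with the membrane protein gene LAMP2 1.85-fold higher, PSAP 1.46-fold and the protease gene CTSB 1.48-fold. Of 24 genes on the list of vesicle trafficking partners of optineurin, 7 rose, 2 fell and 15 did not pass (median 0.10, camera adjusted p = 0.465). The exocyst gene EXOC1 was 1.37-fold higher and the transferrin receptor gene TFRC 1.80-fold lower. CYLD, a deubiquitinase gene of NF-kB signalling rather than of trafficking, was also on this list and was 1.84-fold lower.

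Of 12 tested genes of antigen presentation, 5 rose, 1 fell and 6 did not pass (median log2 fold change 0.32, camera adjusted p = 0.134), and adjusted over the list alone 6 rose and 1 fell. The 5 that rose belong to MHC class II: CIITA, the transactivator gene of that class, rose 16.5-fold from 0.880 ± 0.248 to 14.8 ± 8.31 CPM (SD, n = 4; edgeR adjusted p = 0.000217), and CD74, the invariant chain gene, from 12.1 ± 3.91 to 276 ± 276 CPM. The log2 fold change of CD74 was 4.50 (SE 0.73) and 3.58 without E50K replicate 1, where CD74 was highest. HLA-DRB1 and HLA-DRA rose from 0.188 to 5.36 and from 0.0412 to 1.65 CPM. Their log2 fold changes, 4.63 and 4.96, became 5.68 and 6.003 without control replicate 2 and 3.63 and 4.30 without E50K replicate 1, and the counts of both genes are uncertain because the annotation places them on 7 and 8 sequences. The list passed camera without E50K replicate 4 or E50K replicate 5 (adjusted p = 0.0203 and 0.0499), within 0.00216 to 0.33 over the alternatives with the preset correlation.

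Of 29 interferon response genes, 8 rose, 7 fell and 14 did not pass (median log2 fold change -0.13, camera adjusted p = 0.814), and 9 rose and 7 fell adjusted over the list alone. IFIT2 rose 2.83-fold and MX2 4.38-fold, both antiviral effector genes, while IFITM1 fell 2.85-fold and OAS2 from 1.91 to 0.169 CPM. Of 26 reactive astrocyte genes, 8 rose, 9 fell and 9 did not pass (median -0.007, camera adjusted p = 0.812): the protease inhibitor gene SERPINA3 rose 4.89-fold and S100A10 2.40-fold, while S1PR3, a sphingosine phosphate receptor gene, fell 2.19-fold. Of 13 complement genes, 4 rose, 2 fell and 7 did not pass (median 0.27, camera adjusted p = 0.115), with SERPING1, the gene of the C1 inhibitor, 1.97-fold higher and CD55, a complement regulator gene, 2.57-fold lower. Without both libraries of replicate 5 the complement list passed with a median of 0.472 (camera adjusted p = 0.0383), within 0.0313 to 0.357 over the alternatives with the preset correlation.

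Of 27 extracellular matrix genes, 11 fell, 7 rose and 9 did not pass (median log2 fold change -0.15, camera adjusted p = 0.216). With the replicate block and without replicate 2 the list passed with a median of -0.203 (camera adjusted p = 0.0275), within 0.0275 to 0.367 over the alternatives with the preset correlation. The basement membrane collagen genes COL4A1 and COL4A2 fell 5.41-fold and 4.00-fold, COL4A1 from 1525 ± 510 to 282 ± 27.8 CPM (SD, n = 4), whereas the tenascin gene TNC rose 3.37-fold and BCAN, the gene of the brain proteoglycan brevican, 4.83-fold. Of 25 secreted neurotrophic and synaptogenic factors, 8 rose, 8 fell and 9 did not pass (median 0.06, camera adjusted p = 0.347). The heparin-binding growth factor gene MDK rose 3.17-fold and the thrombospondin gene THBS2 5.64-fold, and BDNF, the gene of brain-derived neurotrophic factor, fell 3.71-fold.

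Stress lists did not pass camera with all 8 libraries. Without both libraries of replicate 1, the unfolded protein and integrated stress response list passed with a median log2 fold change of -0.41 (camera adjusted p = 0.0496, within 0.0496 to 0.61), and so did the immediate early and heat shock list with -0.52 (0.0457, within 0.0457 to 0.855). Of 25 genes of the unfolded protein and integrated stress responses, 9 fell, 2 rose and 14 did not pass (median log2 fold change -0.06, camera adjusted p = 0.274), among them the endoplasmic reticulum chaperone genes HSPA5 (from 1085 to 721 CPM) and HSP90B1 (1.79-fold lower), with PSAT1, of serine synthesis, 1.95-fold higher. Of 21 oxidative stress response genes, 6 rose, 1 fell and 14 did not pass (median 0.07, camera adjusted p = 0.234), including the metallothionein genes MT1E (7.18-fold) and MT2A (2.33-fold) and the cystine transporter gene SLC7A11 (3.13-fold). Of 22 p53, senescence and apoptosis genes, 8 fell, 2 rose and 12 did not pass (median -0.17, camera adjusted p = 0.234), with the nuclear lamina gene LMNB1 2.48-fold lower. Of 14 immediate early and heat shock genes, 4 fell, 2 rose and 8 did not pass (median -0.33, camera adjusted p = 0.34), with FOS 2.70-fold higher and the phosphatase gene DUSP1 at a log2 fold change of -2.39, which became -3.29 without E50K replicate 1. Of 34 ribosomal protein genes 32 did not pass; RPL10, whose exons overlap another gene by 42.7%, was 1.29-fold higher and RPL35 1.24-fold lower, 0 passed adjusted over the list alone, and RPL35 lost its call without any 1 of 6 libraries (adjusted p 0.0518 to 0.0754). The median of this list was -0.003 and its mean 0.03, with camera pointing up (adjusted p = 0.812).

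Markers of other neural cells were mixed. Of 19 neuron markers, 4 rose, 3 fell and 12 did not pass (median log2 fold change 0.11, camera adjusted p = 0.812): the growth cone gene GAP43 rose 2.37-fold and the neurofilament gene NEFL fell 2.31-fold. Of 8 oligodendrocyte lineage markers, 4 rose, 1 fell and 3 did not pass (median 0.42, camera adjusted p = 0.0669). Beside OLIG1, OLIG2 rose 5.22-fold and PDGFRA, a receptor gene of oligodendrocyte precursors, 2.65-fold, while the myelin gene MBP fell 7.75-fold. Of 10 neural progenitor markers, 3 rose, 3 fell and 4 did not pass (camera adjusted p = 0.896), with SOX2 1.71-fold higher and ASPM, a mitotic spindle gene, 4.51-fold lower; the median was -0.20, the mean 0.05 and the camera direction down. Of 13 forebrain identity genes, 5 rose, 1 fell and 7 did not pass (median 0.38, camera adjusted p = 0.15), with FEZF2 5.78-fold and LHX2 2.15-fold higher and EMX2 4.83-fold lower. Of 6 retinal markers, 2 rose, BEST1 and RLBP1, and 4 did not pass (median 0.71, camera adjusted p = 0.171). Of 3 hindbrain and spinal cord genes tested, 1 fell, HOXD8, with a log2 fold change of -4.36 that became -6.47 without E50K replicate 1 and -3.73 without E50K replicate 2 (median -1.28, camera adjusted p = 0.134). Without E50K replicate 1 the oligodendrocyte and forebrain lists passed (camera adjusted p = 0.0364 and 0.0406), within 0.0121 to 0.139 and 0.031 to 0.244 over the alternatives with the preset correlation.

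Markers of cells outside the neural lineage were mostly low in both groups, and more fell than rose. Of 9 fibroblast and mesenchymal markers, 5 fell, 1 rose and 3 did not pass (median log2 fold change -0.76, camera adjusted p = 0.102). The fibrillar collagen gene COL1A1 fell from 201 ± 127 to 6.62 ± 5.76 CPM (SD, n = 4), with a log2 fold change of -4.92 that became -5.72 without E50K replicate 1, and COL1A2 had -2.67, which became -3.44 without E50K replicate 2. Without either of these libraries the list passed (camera adjusted p = 0.0377 and 0.0468), within 0.00273 to 0.127 over the alternatives with the preset correlation. Of 5 endothelial markers, 3 fell and 2 did not pass (median -2.03, camera adjusted p = 0.0497; adjusted p = 0.348 with an estimated correlation). TEK fell from 11.4 to 0.426 CPM and CLDN5 from 4.69 to 1.14 CPM. The call of the list was lost without control replicate 1 or E50K replicate 1 (camera adjusted p = 0.0743 and 0.0938), within 0.000549 to 0.14. It was also lost with DESeq2 size factors (0.0549), library size scaling (0.0564), limma-voom (0.13) and no filter (0.117, with a median of -0.95).

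Of 2 tested markers of pluripotent cells, DPPA4 fell 19.2-fold from 11.6 ± 2.38 to 0.608 ± 0.141 CPM (SD, n = 4) and DNMT3B did not pass (median log2 fold change -2.35, camera adjusted p = 0.00218; adjusted p = 0.202 with an estimated correlation); with limma-voom the list's call was lost (adjusted p = 0.13, within 0.000976 to 0.13). Of 7 epithelial and choroid plexus markers, 3 fell, 1 rose and 3 did not pass (median -0.96, camera adjusted p = 0.17, and 0.0407 without control replicate 4, within 0.00334 to 0.33): CLIC6, a chloride channel family gene, fell from 15.8 to 0.174 CPM, and FOLR1, a folate receptor gene, rose 3.71-fold. Of 6 muscle markers, 2 fell and 4 did not pass (median -0.92, camera adjusted p = 0.258). Of these, TNNT1 lost its call without E50K replicate 2 (adjusted p = 0.054) and ACTA2, whose exons overlap other genes by 32.7%, without E50K replicate 5 or any 1 control (adjusted p 0.0562 to 0.104) and with no filter (0.0954). Of 6 neural crest and Schwann markers, 2 rose, 1 fell and 3 did not pass (median 0.50, camera adjusted p = 0.216), and 3 rose and 1 fell adjusted over the list alone. The receptor gene ERBB3 rose 6.29-fold, and the fall of PMP22 (1.25-fold lower) lost its call without any 1 of 6 libraries (adjusted p 0.0809 to 0.126), with upper quartile scaling (0.0632) and with no filter (0.0562). Of the 12 microglia and macrophage markers only CD68 was tested. This gene stood at 7.45 ± 3.24 CPM in control and 3.28 ± 1.90 CPM in E50K (SD, n = 4) and did not pass over all genes (edgeR adjusted p = 0.0524). Adjusted over the list alone 1 fell, but with a single tested gene that is its unadjusted p. CD68 passed with DESeq2 (0.0124), without E50K replicate 1 (0.0081) or control replicate 2 (0.0426), and with DESeq2 size factors or library size scaling (0.0498 and 0.0463), within 0.00666 to 0.289. The list of protein-coding mitochondrial genome genes was not analysed here.

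Median changes per autosome were small. The largest median log2 fold change of a chromosome was -0.09, over 145 genes of chromosome 21 (permutation test, adjusted p = 0.438 against 10000 random gene sets matched on expression). On chromosome 12 the median over 791 genes was -0.065 (permutation p = 1e-04, the smallest that the draws can give; adjusted p = 0.0022). The median over all tested genes was 0.016.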

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

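No test in this part was chosen after the result was seen, though some of the genes covered were picked later to describe their list. In 424 groups of 4 values, for named genes, list scores and library measures, 21 values (4.95%) lay far from the other libraries of their group by Dixon's test, where chance flags about 1 in 20 groups, or 21.2 here. Of these, 9 were genes in E50K replicate 1, the library apart on the second principal component.

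In E50K replicate 1, GFAP was lowest at 1836 CPM, against 4232 to 4340 in the other E50K libraries. IL6 was highest at 23.7 CPM against 0.0751 to 3.50, and IL1A at 0.613 CPM against 0.0376 to 0.135. NFKB1 was highest at 23.1 CPM and NDRG1 at 51.7 CPM, against at most 17.5 and 20.2. MAP1LC3C, a gene of the LC3 family of autophagy proteins, was at 89.5 CPM, and FOXC1 at 6.57 CPM. OPTN was at 203 CPM, against 141 to 148. CDH5, an endothelial cadherin gene, was at 0 CPM, where the others were at 0.113 to 0.135.

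In control replicate 5, OPTN was highest at 216 CPM against 164 to 166, SLC12A2 at 93.8 CPM and OLIG1 at 0.175 CPM. ATP1B2 was lowest there at 142 CPM. The NF-kB score of this library was 1.60, above 0.78 to 0.89 in the other controls. In control replicate 4, PCDHGB7 was highest at 29.5 CPM, and the oxidative phosphorylation score was lowest at 0.021. Control replicate 2 had the highest control total, 59524917 counts, and the highest LUM, 31.9 CPM.

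In E50K replicate 2, KCNA1 was at 0.103 CPM where the other E50K libraries were at 0, and CPQ at 0.265 CPM. In E50K replicate 4, BNIP3 was highest at 105 CPM.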

How the results depend on the processing

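The alternatives with thinned counts and with the cell cycle score were chosen after the result was seen. Across scalings, filters and tools, 2810 to 3344 genes rose and 2786 to 3418 fell, and 92.6% to 99.9% of the genes called were called again; rises made up 46.3% to 54.6% of calls across scalings. An adjusted p under 0.01 left 1844 and 1897, and a 2-fold minimum 1082 and 1143, by construction. With 1 library left out, 2471 to 3567 rose and 2441 to 3678 fell; with both libraries of a number left out, 1910 to 3399 and 1890 to 3490, with fewer samples. Thinning to the smallest total gave 3023 and 2970. With the cell cycle score as a covariate, edgeR called 3 rises (CBLN4, PCDHGB6 and USP51) and 0 falls, with 749 genes at an unadjusted p under 0.05; the score correlates at -0.94 with group, which leaves little of the group to test.

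Equal numbers follow the letters exp in both groups' labels, which do not say what is shared, and were not taken as pairs: deviations of equal numbers correlated at 0.14, 0.22 and 0.28 for replicates 1, 2 and 4 but at -0.064 for replicate 5, and not every library correlated best with its own number. The replicate block gave 3114 rises and 3117 falls. With the block and a number left out, 1776 to 3550 rose and 1904 to 3562 fell, with 1974 rises without replicate 2. Lists called numbered 13 with the block, 3 of them beyond the 10 otherwise called, oligodendrocyte lineage, fibroblast and mesenchymal, and antigen presentation (camera adjusted p = 0.015, 0.0215 and 0.0204), and 20 by fry with the block.

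Of the fixed lists, 0 were called with an estimated correlation and 21 by fry, against 8 to 14 under the alternatives that kept camera and its preset correlation. For OPTN the log2 fold change ran from -0.33 (without replicate 1) to 0.008 (without replicate 5), and the cause was not tested. The largest chromosome median was -0.131 with library size scaling, -0.128 with the block and -0.126 without replicate 4, and without replicate 5 it was 0.054, on chromosome 5; the cause was not tested. Of 157 named genes called, 134 stayed called in every other fit at the same threshold, the covariate aside, 23 lost the call in at least 1, and 0 changed direction. With both libraries of a number left out, RLBP1 lost its call without replicate 2 or 5, RPL10 without 2 or 4 and PDGFRA without 5. CD55, DIO2, DUSP1, EMX2, FAM69C, HSPA5 and ULK2 lost theirs only with the block and a number left out, and FOXC1 also without any 1 of 6 libraries.

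Results that changed direction had not been called, and the cause was not tested. PECAM1 was at -0.261 with voom, -0.318 with the block in DESeq2, -0.168 to 0.745 with libraries left out, and -0.635 and -0.521 with the block without replicates 2 and 5. SQSTM1 ran from -0.193 (without replicate 1) to 0.24, and was at -0.19 with the block and without replicate 1. Lists whose camera direction turned with libraries left out had medians of -0.291 to -0.114 for neural progenitor markers (with the block -0.207), -0.06 to 0.082 for ribosomal protein genes (-0.035 and -0.025), -0.027 to 0.346 for neuron markers, -0.048 to 0.189 for lysosome genes (-0.071) and -0.216 to 0.099 for reactive astrocyte genes (0.059). Depth limits genes under about 0.113 CPM, the level of 3 counts in the smallest library.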

Other observations

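The tests of depth, of neural progenitors, of the order of X-linked genes and of alternate copies of the HLA region were chosen after the result was seen, as were the 6 gene lists of this part. Of 36 tested clustered protocadherin genes, which give neurons and glia a surface identity, 16 rose, 1 fell and 19 did not pass, also adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 0.000225; adjusted p = 0.328 with an estimated correlation). The groups overlapped on the score of this list, where E50K replicate 1 was at -0.289 and the controls at -0.575 to -0.12 (exact two-sided permutation p = 0.0857). Some of these genes share exons with other members, as PCDHGB6 and PCDHGB7 do, so single values are uncertain. All 6 tested metallothionein genes, which bind zinc and copper, rose, with MT3, the form named for brain, 6.68-fold higher (median 1.84, camera adjusted p = 5.16e-06; adjusted p = 0.0893 with an estimated correlation), 3 of them shared with the oxidative stress list. Of 18 imprinted genes, 5 fell, 1 rose and 12 did not pass (median -0.12, camera adjusted p = 0.0105; adjusted p = 0.102 with an estimated correlation). PEG10, a gene of retroviral origin, fell 2.60-fold from 4944 ± 627 to 1901 ± 266 CPM (SD, n = 4), and RTL1, beside DLK1 on chromosome 14, fell 5.63-fold. Of 18 genes of GABAergic neurons, 3 rose and 15 did not pass, and 0 passed adjusted over the list alone (median 0.20, camera adjusted p = 0.522, 3 at an edgeR adjusted p under 0.05 over all genes).

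Medians of 10 neighbouring genes passed in 2 places, tested against the value farthest from 0 in either direction in each random order. These p-values concern the order of genes, not the spread between libraries. The highest median of 10 neighbours was 2.27, over the MHC class II region of chromosome 6 (32115268 to 33089696). Of 1000 random orders, 0 held a window as far from 0 (permutation p = 0.000999, the smallest they can give). HLA-DRA, HLA-DRB1 and HLA-DRB5, which lie in this window, stood at 0.0412, 0.188 and 0.142 CPM in control. They passed the filter mainly through the E50K libraries, so a rise was likely once they were tested. The window median rests partly on them, and the random orders do not allow for this. On chromosome 4 (120059424 to 122689156) a window with CCNA2 had a median of -1.68 (permutation p = 0.014). A window on chromosome 2 (164492406 to 166375987) with the sodium channel genes SCN1A, SCN2A, SCN3A and SCN9A, at 1.32, did not pass (permutation p = 0.158).

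Whether chance can account for the main counts was tested with all 35 splits of the 8 libraries. Only the real split, 1 of 35, called 6068 genes, and the highest other split called 0 (3082 at an unadjusted p under 0.05, against 7402 in the real split). This argues against chance for the number of genes, though 1 of 35 is the smallest share the splits can give. Splits that mix the groups put the group difference into the spread, so few calls were likely there. The splits also take the 8 libraries as independent, which the labels do not say. For the number of lists chance is not excluded: 15 of 35 splits called as many lists with camera as the 10 of the real split, and the highest other called 17. For the largest chromosome median, 2 of 35 splits gave a value as far from 0, the highest other at 0.094, so chance is not excluded there either.

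The first pattern is the fall of all cell cycle genes with the rise of astrocyte markers. A difference in depth as the whole cause is argued against, since with the log2 total count of each library in the fit, the group term of the cell cycle score was -2.085 (95% interval -2.755 to -1.415, from the spread between the 8 libraries), against -2.035 without it, and that of the astrocyte score 0.819 (0.531 to 1.108), against 0.827. A smaller share of dividing cells may carry the rise of astrocyte markers, but in a fit of the astrocyte score with the cell cycle score the group term was 0.64 (95% interval -0.198 to 1.478), against 0.827 (SE 0.105) without the cell cycle score. This cannot be told apart, because the cell cycle score correlates at -0.94 with group. Fewer neural progenitors also stay open, since the median of their markers was -0.196 with members going both ways, as do the genotype and a difference between the cell clones, whose number the labels do not give.

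The second pattern is MHC class II. Of 12 listed genes of the class 8 were tested, and all 8 rose (median log2 fold change 4.14, camera adjusted p = 0.000225, and 0.287 with an estimated correlation). HLA-DRA, HLA-DRB1 and HLA-DRB5 stood at 0.0412, 0.188 and 0.142 CPM in control. They passed the filter mainly through the E50K libraries, so their rise adds little. Microglia or macrophages are argued against, since PTPRC, TYROBP, AIF1 and CSF1R together reached at most 0.0611% of the CD74 level in an E50K library. Reads split between copies of the HLA region stay undecided. The smallest log2 fold change among genes on 1 sequence was 4.043 (SE 0.44), for CIITA, but CIITA and CD74 lie outside that region and cannot test it. HLA-DRB5, in the region and on 1 sequence, rose (log2 fold change 4.248, SE 0.847), but from 0.142 CPM in control, near the floor. A response to interferon-gamma is argued against too, for the genes tested. Of 20 listed genes that it induces 14 were tested, 2 of them also in the NF-kB list and 1 in the interferon list. PSMB8, PSMB9 and TAP1 were among those not tested. Of the 14, 8 fell and 1 rose (3 rose adjusted over the list alone), with a median of -1.206 (camera adjusted p = 0.00346, and 0.287 with an estimated correlation). The genotype and a difference between clones stay open, as untested. CD74 ranged from 61.5 to 664 CPM among the E50K libraries.

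The third pattern is a window of 10 X-linked genes (105822543 to 107651026) with a median of -1.24, 6 of them lower and 0 higher. Of 1000 random orders of the tested genes, 269 held a window as far from 0, so the order of genes by chance may account for a window of this length. Falls went on past its end, as in MID2 (log2 fold change -1.412) and PAK3 (-2.153), while PSMD10 (0.022) and TMEM164 (0.353) between them did not pass. These genes were picked after their values were seen, and a run longer than 10 genes was not tested. No biological explanation was tested.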
